A study of Mus musculus with 2 samples.

How the data were processed

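The measurements are long-read RNA sequencing of total RNA from gastrocnemius muscle of 14-day-old female B6CASTF1/J mice, an F1 hybrid of the C57BL/6 and CAST strains. The labels give 1 group of 2 libraries, named biological replicates 1 and 2, and a starting quantity of 2 µg. Each library was used as 1 replicate.

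Per the file headers, the authors deposited for each library a table of raw read counts per transcript model and an annotation file with the exons of each model. The counts were not normalized, and models without a read were not listed in the tables. The notes beside the files name the mouse assembly mm10 (GRCm38), the GENCODE M21 primary assembly annotation and a filtered alignment as the parent of both files. The attributes of the annotation files name TALON, a program that assigns long reads to transcript models. Its version, the aligner and the sequencing platform are not given in the sources used here. The authors' tables place each model in a class. Known models have an annotated intron chain, and incomplete splice matches (ISM) hold part of one. NIC and NNC models are unannotated chains, by the tables' classes those of known splice sites and those with at least 1 other splice site. Some NIC chains hold sites outside GENCODE M21. Genomic models overlap a gene without its splicing, and antisense and intergenic are the tables' classes for models assigned to no annotated gene, although some of these overlap a gene on the same strand. All coordinates are those of the authors' annotation files, counted from 1 on mm10.

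Reads of a gene are the sum over all models the authors assigned to that annotated gene. Models of unannotated loci and the ERCC spike-ins, synthetic RNAs added to the samples, were kept out of gene tests and of the totals for CPM (the reads of a gene scaled to the total over annotated genes). The replicate 1 table held 1316937 reads in 81166 models and that of replicate 2 held 1204188 reads in 74548 models. Annotated genes took 1248854 and 1106450 of these reads, spike-ins 47347 (3.60%) and 41588 (3.45%), and unannotated loci 20736 and 56150. A single read was worth 0.801 CPM in replicate 1 and 0.904 CPM in replicate 2. A count of 0 allows up to 3 reads, which is 2.40 and 2.71 CPM. Intervals of shares are Wilson 95% intervals. Identifiers of unannotated models are given per library, so models were matched between the libraries by their intron chain.

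With a single group there was no test between conditions. The spread between the libraries was measured as the biological coefficient of variation, the square root of edgeR's common dispersion with TMM factors and edgeR's default expression filter, and as correlations across genes of log2(CPM + 1). Genes that differ between the libraries were called by Fisher's exact test, two-sided, on the reads of a gene against those of all other genes. Genes with at least 10 reads in the sum were tested, with Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and an absolute log2 ratio of at least 1 of TMM-scaled CPM with a prior count of 0.5. Such a test compares the reads of these libraries, so its p-value holds no spread between animals. For each gene list the levels, the counts of calls, the calls adjusted over the list alone and the percentile of the list's median log2 ratio among 10000 random lists are given. Random lists had the same size, each member being replaced by a gene drawn from the 50 nearest in mean CPM. Sarcomeric myosin heavy chains were compared as shares of their summed reads by Fisher's exact test.

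Isoform use was tested in genes with at least 50 reads in full splice chains (known, NIC and NNC) in each library, by a two-sided chi-square permutation test with 10000 tables of fixed margins per gene. Internal exons were compared by the reads with both junctions into the exon against reads with the junction that skips it, with at least 20 informative reads in each library and Fisher's exact test. Exons at 10 to 90% inclusion in both libraries are called alternative. Unannotated chains (NIC and NNC) with at least 2 reads in their library of origin were looked up in the other library.

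The lists and tests named above, 23 gene lists with levels, an isoform list of 70 genes and the rule for named genes were fixed before the data were examined. The rule takes the 20 genes with the highest mean CPM, up to 6 members per list in the order of mean CPM and every myosin heavy chain, members of the isoform list in the order of reads, the 15 alternative exons with the most reads and those in the isoform list, the 10 unannotated chains with the most reads, and the 10 genes with the largest ratio in each direction among called genes with at least 20 reads. Genes named outside it are said to have been chosen after their values were seen. A list of 30 fasting and glucocorticoid response genes was added after the data were seen. The other alternatives added then are a correction for transcript length, lists matched on length, gene counts, lists and myosin shares from full splice models alone, protein coding genes alone, and class shares without Atp2a1 or without spike-ins. The length correction subtracts a running median of the log2 ratio over 201 genes ordered by length. The length of a gene is that of its most read full splice model (known, NIC or NNC) over both libraries. The reads are tested by an exact binomial test against the predicted split, and genes without such a model were not tested there.

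Alternatives fixed before were DESeq2 size factors and total scaling, other read minimums, models without the genomic class or known models alone, exclusion of mitochondrially encoded genes, thinning of the deeper library, incomplete matches as chains, other inclusion limits, leaving out each replicate and edgeR's exact test with the common dispersion in place of Fisher's exact test.

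The gene test, the gene lists, isoform use, exon inclusion, the length trend and the coefficient of variation were tested on simulated data with known answers. The other steps were not. For the gene test on 8921 genes, 46.0% of 100 genes changed 2-fold were called, because the log2 limit sits at that size, and 78.0% had an adjusted p under 0.05. All 100 genes changed 4-fold were called, along with 5 unchanged genes. In libraries drawn with the measured coefficient of variation and no true difference, the same test called 1689 of 8831 genes, and since that spread was measured between these libraries, the number does not separate replicate spread from a real difference. For the gene lists, simulated on 3000 genes, 7.5% of 200 random lists fell outside the central 95% and 90.0% of 200 lists shifted by 1 SD fell above it. For isoform use in 400 genes, all of 200 shifts of 30 points were found and 0.5% of 200 unchanged genes were called. For exon inclusion over 1000 exons, 90.5% of 200 shifts of 30 points were found and 0.875% of 800 unchanged exons were called. For the length trend over 6369 genes the median absolute error was 0.03 on the log2 scale. A simulated coefficient of variation of 0.394 came back as 0.362 with edgeR's filter over 5692 genes, as 0.390 without a filter over 14632 genes, and as 0.393 over 6784 genes chosen by their simulated mean. The filter acts on the drawn counts, so the value with it lies below the simulated one.

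The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Paralogs and pseudogenes that can share reads, among them the myosin heavy chains, the globins, ribosomal protein genes and genes named Gm, are reported as uncertain. Reads of unannotated loci enter no comparison and are given as values only. Lexogen spike-ins, which the labels also name, occur under no such name in the count tables and were not analysed here. Some genes that the rule names are left out of the text.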

Results

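The series sequenced full-length transcripts of mouse gastrocnemius, the large calf muscle, at 14 days after birth. Both libraries came from female mice of the hybrid strain B6CASTF1/J and form a single group, so the design holds no contrast between conditions. The measurements answer which genes and which of their splice forms this muscle expressed at this age, and how far the 2 replicates differed. The biosample label of replicate 1 names 3 females and that of replicate 2 a female without a count, and both carry the same donor identifier. Whether either library was a pool of animals is not given in the sources used here. Replicate 1 had 1316937 reads and replicate 2 had 1204188. Each test between the libraries compares those libraries, not conditions. P-values, intervals and floors taken from read counts cover counting error only, and reads without molecular identifiers are not independent molecules. Exceptions are edgeR's exact test, which uses the common dispersion, and tests and intervals over genes, chains, exons or spike-ins.

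Transcripts of fast-twitch contraction and of its energy supply were the most abundant. Atp2a1, the calcium pump of the sarcoplasmic reticulum in fast fibres (chromosome 7, 126444130 to 126463108), had the highest mean, 75695 ± 56406 CPM (SD, n = 2). That rank rested on replicate 1, since in replicate 2 its 35810.0 CPM lay below Acta1 (72383 CPM), Ckm (60042 CPM) and Tnnc2 (52568 CPM). Acta1, skeletal alpha-actin (chromosome 8, 123891769 to 123894751), stood at 71975 ± 576 CPM and Ckm, muscle creatine kinase (chromosome 7, 19404776 to 19422841), at 60620.1 ± 817 CPM. The fast troponin C gene Tnnc2 (36884 ± 22181 CPM), the myosin light chain genes Mylpf (28547 ± 10226 CPM) and Myl1 (17848 ± 6548 CPM), tropomyosin Tpm1 (24629 ± 3169 CPM) and the fast myosin heavy chain Myh4 (17191 ± 8306 CPM) came next. Slc25a4, Aldoa, Eno3, Casq1, Ldha, Atp5b, Actn3, Mybpc2, Cox4i1, Ak1, Pgam2 and Pvalb completed the 20 most abundant genes, with means from 12516 CPM for the ADP/ATP carrier Slc25a4 down to 4486 CPM for the calcium buffer Pvalb. These 20 genes held 44.2% of the gene reads of replicate 1 and 39.8% of those of replicate 2. Atp2a1 was higher in replicate 1, at 11.6% of its gene reads against 3.58% in replicate 2 (log2 ratio 1.41), and Tnnc2 was higher in replicate 2 (log2 ratio -1.59). Both passed Fisher's exact test, whereas Acta1, Ckm and Eno3 lay within a log2 ratio of 1.

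The libraries differed by transcript length, which bears on each gene group described here. The mean model length per read was 2336 bases in replicate 1 and 1510 bases in replicate 2. The median log2 ratio of replicate 1 to replicate 2 was -1.64 over 221 genes of at most 500 bases, -1.23 over 800 genes of 500 to 1000 bases and -0.39 over 2203 genes of 1000 to 2000 bases. It was 0.24 over 3630 genes of 2000 to 4000 bases and 0.47 over 1999 longer genes. All ratios are on the TMM scale, which lies -0.28 (log2) from scaling by the total, as DESeq2's factors lie -0.22 from it. No ratio called here, each at least 1 in size, changes its sign by such a shift.

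**Figure D1:**
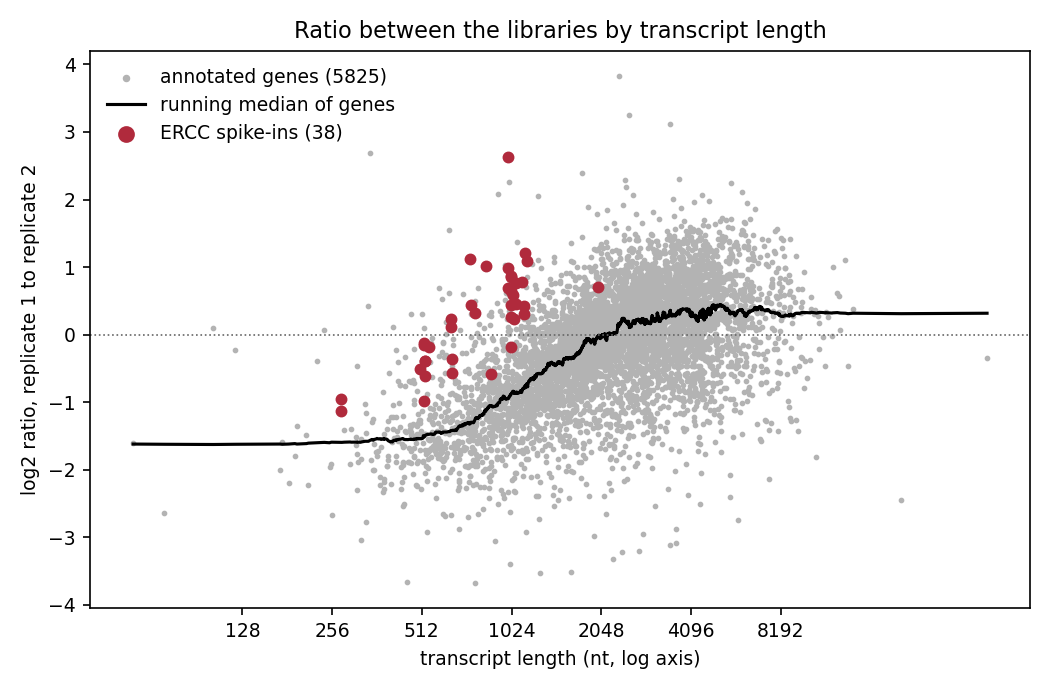
Log2 ratio of replicate 1 to replicate 2 (vertical) against model length in bases on a log axis, with 1 grey point per gene with at least 10 reads in each library, their running median in black and 38 ERCC spike-ins in red, as the ratio of their shares of spike-in reads. Short genes lie below 0 and long genes above, and the spike-ins rise with length as well.

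Fast-fibre genes outweighed slow-fibre genes in both libraries. The 15 genes of the fast contractile list held 23.7% ± 3.84 of gene reads (SD, n = 2) and the 12 of the slow list 0.688% ± 0.227. The fast list took 98.0% of the reads of both lists in replicate 1 (95% Wilson interval 98.0 to 98.1%) and 96.1% in replicate 2 (96.0 to 96.2%), a mean of 97.1% ± 1.37. Among slow-fibre genes the highest means were those of the slow troponin T gene Tnnt1 (2171 ± 2433 CPM), slow myosin-binding protein Mybpc1 (1285 ± 1079.6 CPM), the slow myosin heavy chain Myh7 (769 ± 207 CPM) and Tnnc1 (744 ± 546 CPM). In replicate 1 Mybpc1 (2048 CPM) and Myh7 (915 CPM) lay above Tnnt1 (451 CPM). Between the libraries, 4 of 15 fast genes were higher in replicate 1 and 5 in replicate 2, and the counts adjusted over the list alone were again 4 and 5. Of 11 slow genes tested, 1 was higher in replicate 1 (Mybpc1, log2 ratio 1.69) and 6 were higher in replicate 2, again 1 and 6 adjusted over the list alone. With the length trend removed these became 5 and 0 fast genes and 1 and 1 slow genes, and the calls of Tnnc2, Mylpf, Myl1, Pvalb and Tnnt3 ended. Tnnt1 stood out at 563 against 4306 reads, but its full splice models held 78 and 101 reads, and in those it was not called.

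Genes of the developing muscle were low beside the adult set. The perinatal list held 0.240% ± 0.0362 of gene reads (SD, n = 2), most of it cardiac alpha-actin Actc1 at 1952 ± 441 CPM. The myogenic factor Myog stood at 149 ± 0.505 CPM, and the perinatal and embryonic myosin heavy chains Myh8 and Myh3 at 42.9 ± 9.54 and 21.9 ± 4.13 CPM. In this list 0 of 13 tested genes were higher in replicate 1 and 3 in replicate 2, the same counts as adjusted over the list alone. They included Sln, sarcolipin, an inhibitor of the calcium pump, with 4 against 141 reads, and Myl4, the atrial and embryonic light chain, with 24 against 50. The call of Myl4 ended with the length trend removed (log2 ratio -0.44), and its full splice reads, 15 and 6, had the other direction. Tnnt2 had 0 and 2 full splice reads. The list of Z-disc and M-band scaffold genes held 8.45% ± 0.214 of reads, most of it Acta1 at 71975 ± 576 CPM. The intermediate filament gene Des came next (3699.9 ± 63.0 CPM). Acta1, an actin rather than a scaffold gene, thus made up most of the level of this list. None of its 20 genes was higher in replicate 1 and 2 were higher in replicate 2, Csrp3 (log2 ratio -1.88) and Xirp2 (-1.17), by either adjustment, over all genes or adjusted over the list alone. Csrp3 lost its call with the length trend removed (log2 ratio -0.82).

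Excitation-contraction coupling genes held 0.898% ± 0.367 of gene reads (SD, n = 2), among them the calcium-binding protein gene Hrc (3187 ± 3463 CPM), Sypl2 (1427 ± 176 CPM) and triadin, Trdn (1379 ± 839 CPM). Hrc was the highest in replicate 2 (5636 CPM) and lay below Sypl2, Bin1 and Trdn in replicate 1 (738 CPM). In known models alone the list held 3269.7 CPM against 8977 CPM in all models. Of 16 tested, 2 were higher in replicate 1 (the sodium channel Scn4a and the chloride channel Clcn1, log2 ratios 1.43 and 1.09) and 2 in replicate 2 (Hrc, -3.22, and Trdn, -1.61), unchanged when adjusted over the list alone. In full splice models Hrc had 67 and 172 reads of its 922 and 6236, and Trdn had 227 and 247 and was not called. Cacna1s, Stac3, Jph1 and Jph2 were called as higher in replicate 1 there, which makes 6 and 1. The call of Clcn1 ended with the length trend removed (log2 ratio 0.80). Neuromuscular junction genes held 0.04998% ± 0.00972, with the acetylcholinesterase gene Ache at 65.6 ± 34.0 CPM and the receptor subunits Chrna1 and Chrne at 49.4 ± 7.19 and 41.3 ± 6.07 CPM. None of the 10 junction genes tested passed, also none adjusted over the list alone.

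Phosphate transfer held the most reads among the metabolic groups. The glycolysis list held 4.16% ± 0.481 of gene reads (SD, n = 2), with Aldoa (9203 ± 2672 CPM), Eno3 (8692 ± 157 CPM), Ldha (6976 ± 8.18 CPM) and Pgam2 (4698 ± 1913 CPM). Of 18 tested, 3 were higher in replicate 1 (Phka1, 1.53, Hk2, 1.06, and Hk1, 1.62, as log2 ratios) and 1 in replicate 2 (Pgam2, -1.14), the same counts as adjusted over the list alone. Phka1 alone kept its call with the length trend removed, where Pgam2 was at -0.02 and Hk2 at 0.72. Hk1 stayed at 1.38 there and missed the adjusted p alone (0.094, exact binomial test). Creatine and phosphate transfer genes held 6.77% ± 0.179, nearly all Ckm, and 2 of 9, Gamt and Gatm, which make creatine, were higher in replicate 2 by both adjustments, over all genes and adjusted over the list alone. With the length trend removed 1 and 1 passed, Ckmt2 as higher in replicate 1 (log2 ratio 1.18) and Gatm in replicate 2, and Gamt lost its call (-0.52). Nuclear genes of oxidative phosphorylation held 3.88% ± 0.870, with Atp5b (5269 ± 71.1 CPM), Cox4i1 (4978 ± 2856 CPM), Atp5a1 (2738 ± 1370.3 CPM) and Ndufa4 (2703 ± 1684 CPM). Among these 26 genes, 11 were higher in replicate 2 and 0 in replicate 1, again 11 and 0 adjusted over the list alone. None of the 11 kept its call with the length trend removed, and Cycs, cytochrome c, not called before, passed as higher in replicate 2.

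Mitochondrially encoded transcripts held 0.0666% of gene reads in replicate 1 and 0.245% in replicate 2, a mean of 0.156% ± 0.126 (SD, n = 2), with mt-Cytb at 697 ± 713 CPM and mt-Co1 at 387 ± 217 CPM. Whether such reads were filtered before counting is not given in the sources used here, so the share is that of the tables, not a level in the muscle. All 9 that passed, of 11 tested, were higher in replicate 2, the same 9 in number adjusted over the list alone, and 5 passed with the length trend removed. Ribosomal protein genes held 1.62% ± 0.866, and 32 of 43 were higher in replicate 2 and 0 in replicate 1, again 32 and 0 adjusted over the list alone. With the length trend removed 5 were higher in replicate 2 and 1 in replicate 1. Rps14 and Rpl5 were higher in replicate 2 (log2 ratios -1.74 and -2.16), and with the trend removed Rps14 was not called. Ribosomal protein genes have many processed pseudogenes, so single members are uncertain.

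Growth and proliferation genes followed. The imprinted growth list held 0.389% ± 0.0166 of gene reads (SD, n = 2), mostly the long RNA H19 (1622 ± 234 CPM), Gnas (979 ± 147 CPM) and the cell cycle inhibitor Cdkn1c (774 ± 19.3 CPM), whereas Igf2 stood at 114 ± 39.8 CPM. Of its 13 tested genes 5 were higher in replicate 2 (Igf2, Dlk1, Meg3, Rian and Peg3, with log2 ratios of -1.01 to -3.59). In replicate 1, 0 were higher, and the counts adjusted over the list alone were the same. The call of Igf2 ended with the length trend removed (log2 ratio -0.07) and its full splice reads, 14 and 5, had the other direction. Meg3, Rian and Peg3 were not called in full splice models. Cell cycle genes held 0.0211% ± 0.00114, with the proliferation marker Mki67 at 3 reads in each library, and 0 of 12 tested passed, likewise 0 adjusted over the list alone. Stress and immediate early genes held 0.0986% ± 0.0107, led by the small heat shock proteins Cryab (533 ± 128 CPM) and Hspb1 (255 ± 62.6 CPM). Nr4a1 (84 and 13 reads) and Zfp36 (10 and 0 reads) were higher in replicate 1, so 2 of 14 passed and 0 were higher in replicate 2, with the same counts adjusted over the list alone. With the length trend removed the log2 ratio of Zfp36 stayed at 3.74 and only its adjusted p (0.0504, exact binomial test) missed the limit.

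**Figure D2:**
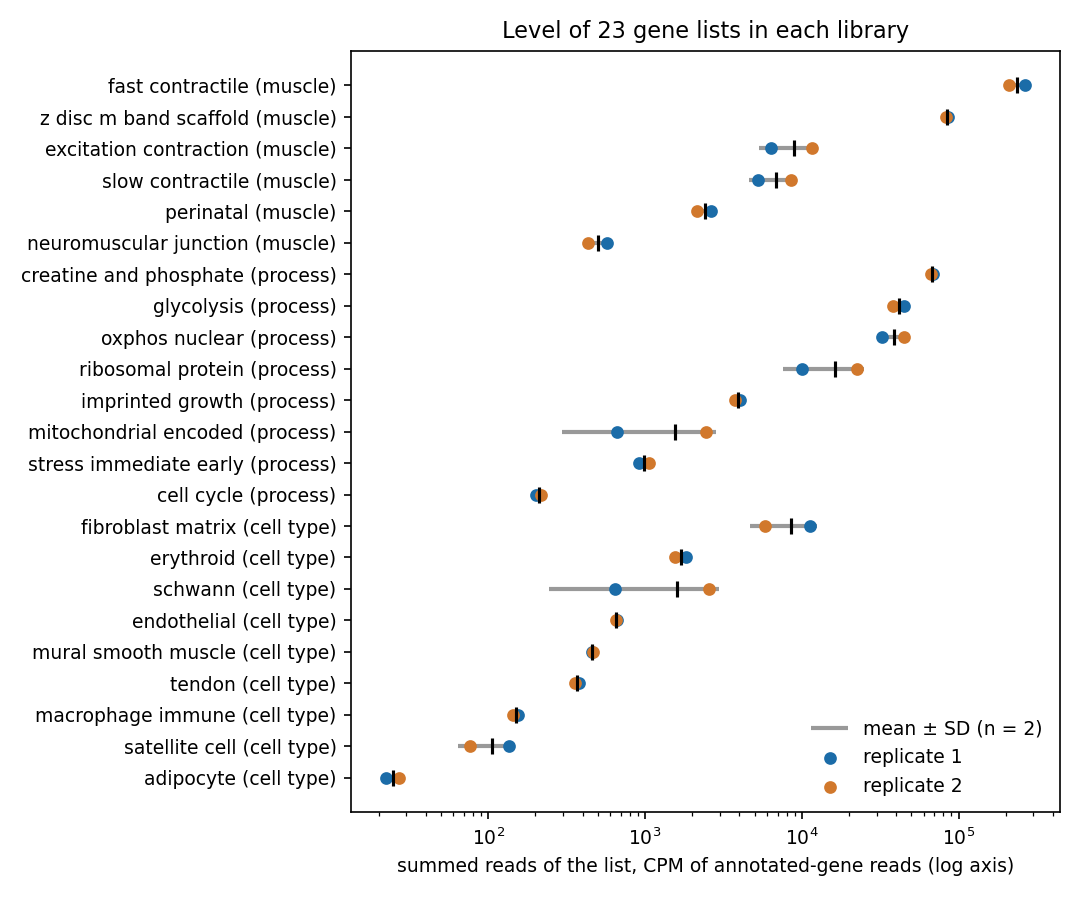
Summed reads of each gene list in CPM on a log axis, with a point for each library and a bar for the mean ± SD (n = 2). The fast contractile list is the highest at a mean of 236670 CPM, which is 23.7% of gene reads.

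Markers of other cell types marked out the rest of the tissue. Fibroblast and matrix genes held 0.856% ± 0.389 of gene reads (SD, n = 2), with the collagens Col3a1 (2718 ± 1439 CPM) and Col1a1 (2609.9 ± 1746 CPM) and Sparc (948 ± 29.98 CPM). Col1a1 and Fn1, fibronectin, were higher in replicate 1 (log2 ratio 1.24 for Fn1), 2 of 18, with 0 in replicate 2 and the same counts adjusted over the list alone. Both calls ended with the length trend removed (log2 ratios 0.84 and 0.92). Erythroid genes held 0.169% ± 0.0190, nearly all globin, with Hba-a1 at 891 ± 4.31 CPM and Hbb-bs at 442 ± 105 CPM, which are uncertain because the globin genes are near copies. Alas2, the haem synthesis enzyme of red cells, was the 1 of 5 higher in replicate 1, also adjusted over the list alone, and all 5 were higher in replicate 1 with the length trend removed. Schwann cell genes held 0.160% ± 0.135. In this list 4 of 9 tested genes were higher in replicate 2 and 0 in replicate 1, and 5 and 0 adjusted over the list alone. They included the myelin genes Pmp22 and Mbp and the calcium-binding S100b (log2 ratios -1.43, -1.38 and -2.89).

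Endothelial, mural, tendon, immune, satellite cell and fat markers had few reads. Endothelial genes held 0.0658% ± 0.00110 (SD, n = 2), with Fabp4 at 168 ± 71.4 CPM and Cldn5 at 136 ± 21.4 CPM. Pecam1 and Cdh5 were higher in replicate 1 and Fabp4 in replicate 2, and the counts adjusted over the list alone were 4 and 1. Mural and smooth muscle genes held 0.0462% ± 0.000228. Myh11 was higher in replicate 1, Acta2 and Cnn1 were higher in replicate 2, and the counts adjusted over the list alone were 1 and 3. Tendon genes held 0.0368% ± 0.00135, and of 9 tested the tendon markers Tnmd and Scx were higher in replicate 2 (log2 ratios -1.21 and -1.57) and 0 in replicate 1, as when adjusted over the list alone. Macrophage and immune genes held 0.0150% ± 0.000703, and 1 of 9, Mrc1, was higher in replicate 1 and 0 in replicate 2, as when adjusted over the list alone. Satellite cell genes held 0.0106% ± 0.00419, with Pax7 at 3 and 1 reads, and 0 of 6 passed by either adjustment, over all genes or adjusted over the list alone. Adipocyte genes held 0.00248% ± 0.000332, with Adipoq at 5 and 3 reads, and the 1 gene tested, Cfd, was higher in replicate 2, also adjusted over the list alone. Cdh5, Fabp4, Tnmd and Scx were within a log2 ratio of 1 with the length trend removed, while Mrc1 (log2 ratio 1.29) and Cfd (-1.48) missed the adjusted p alone.

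Medians of 6 of the 23 lists lay outside the central 95% of random lists, against 1.15 expected at the nominal rate. In simulation 7.5% of 200 random lists fell outside. Random lists were drawn gene by gene, so the expected number does not cover lists whose members vary together. Glycolysis (percentile 99.7), fibroblast and matrix (99.9) and the Z-disc list (98.7) were at the replicate 1 end. The mitochondrially encoded (0.00), ribosomal protein (0.17) and Schwann lists (0.13) were at the replicate 2 end. With random lists matched on length as well, 8 lists lay outside. Fast contractile (97.7), glycolysis (98.3), stress (99.2) and erythroid (100) were high, and mitochondrially encoded (0.01), Schwann (0.06), imprinted growth (1.17) and cell cycle (2.16) were low. The trend removed also changed the calls in replicate 1 and replicate 2 to 3 and 1 in the Z-disc list, 3 and 0 in the stress list, 1 and 1 in the fibroblast list and 0 and 2 in the cell cycle list. Full splice models gave 7 and 1 in the Z-disc list, 5 and 0 in the fibroblast list, 5 and 1 in glycolysis, 4 and 0 in the endothelial list, 2 and 1 in the perinatal list, 0 and 1 in the imprinted list and 0 and 2 in the Schwann list.

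Among the sarcomeric myosin heavy chains, which set fibre type, the fast type 2B gene Myh4 held the largest share. It took 71.9% of the 40079 myosin heavy chain reads in replicate 1 (95% Wilson interval 71.4 to 72.3%) and 82.9% of 15100 in replicate 2 (82.3 to 83.5%), a mean of 77.4% ± 7.82 (SD, n = 2). Myh1, of type 2X fibres, took 15.04% ± 8.11, Myh7, of slow fibres, 3.70% ± 1.21, and Myh2, of type 2A fibres, 3.51% ± 1.03. Myh8 and Myh3 took 0.210% ± 0.0779 and 0.108% ± 0.0436, Myh6 0.0179% ± 0.00651, Myh7b had 3 and 1 reads and Myh13 had 2 and 0. Myh15 had 0 reads, which allows a share of up to 0.00958% in replicate 1 and 0.0254% in replicate 2 as upper Wilson bounds. Shares differed between the libraries for Myh4 (Fisher's exact test, two-sided, adjusted p = 2.4e-165), Myh1 (1.1e-240), Myh7 (1.4e-21), Myh2 (9.0e-16) and Myh8 (0.020), and not for Myh3 (0.071). In full splice reads alone the Myh4 difference had the other direction, 71.5% in replicate 1 and 65.1% in replicate 2 (adjusted p = 1.1e-13, Fisher's exact test), and Myh7 stood at 3.44 and 11.9%. In these reads Myh2 (3.24 and 3.25%) and Myh8 (adjusted p = 0.87) did not pass, and Myh3 did (0.022). Full splice reads made up 67.0% of the Myh4 reads in replicate 1 and 18.4% in replicate 2. The skeletal members are near copies in a cluster on chromosome 11, so partial reads could be split among them.

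**Figure D3:**
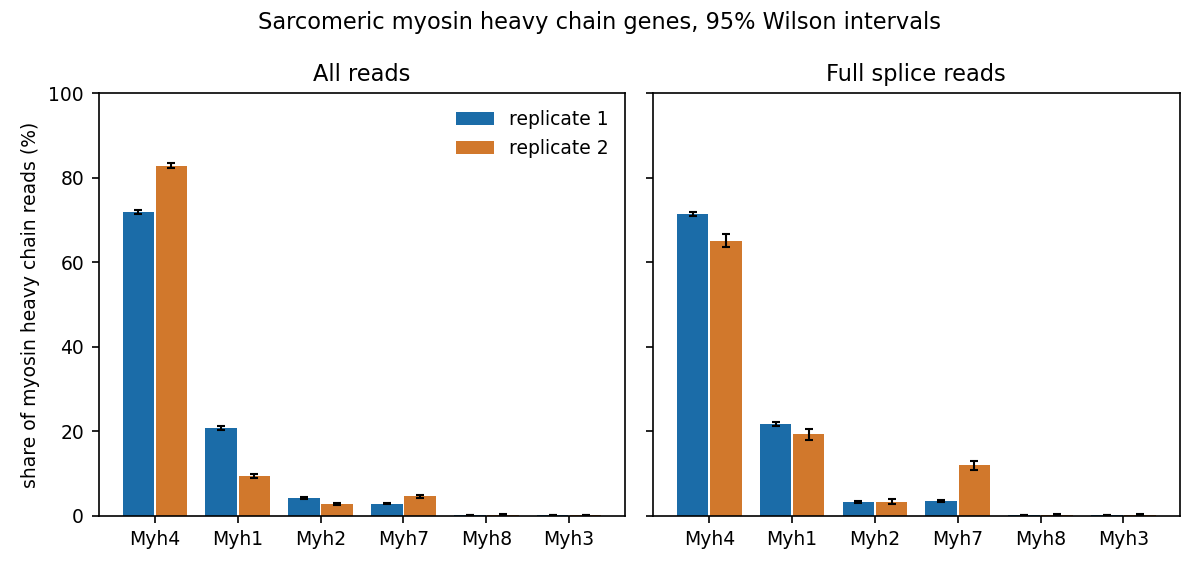
Share of myosin heavy chain reads held by each gene in each library, in percent with 95% Wilson intervals, from all reads and from full splice reads. Myh4 is the largest in all cases, at 71.9 and 82.9% of all reads and at 71.5 and 65.1% of full splice reads.

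Detection reached 5850 annotated genes with at least 10 reads in each library, of which 5645 were protein coding, and 12183 genes with at least 1 read in each. A further 1687 genes had a read in replicate 1 alone and 1877 in replicate 2 alone, yet with at least 10 reads on the present side these were 19 and 21. Across 15747 genes with a read, log2(CPM + 1) of the libraries had a Pearson's r of 0.894 and a Spearman's rho of 0.865, and across the 5850 genes these were 0.866 and 0.799. Genes are not independent replicates, so no p-value is given. The biological coefficient of variation was 0.394 over 5753 genes (block jackknife SD 0.00419 over genes), and 0.296 with the length trend removed.

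Among the genes with the largest differences between the libraries, Pdk4, the kinase that shuts off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), had 1634 reads in replicate 1 and 136 in replicate 2 (log2 ratio 3.12). Arrdc2, of the arrestin-domain family, had 263 and 13 (log2 ratio 3.83), and the mitochondrial ATP-Mg carrier Slc25a25 had 256 and 19 (3.26). Unc5a had 24 and 0 reads, 5.82-fold higher against a floor of 3 counts, with a lower 95% counting limit of 4.38-fold. Depp1 had 47 and 3 reads, a ratio of 11.4 with a 95% counting interval of 3.67 to 57.3. Gm28006, a small RNA of 122 bases, and Gm45837, Pdpr, Camsap1 and Lyn were also among the 10 largest, the last with 27 and 2 reads. In replicate 2 the calcium pump inhibitor Sln (chromosome 9, 53850164 to 53854560) had 141 reads against 4 in replicate 1 (log2 ratio -5.43). The cardiac troponin T gene Tnnt2 (22 reads) and the microRNA host locus Mir1a-1 (21 reads) had 0 reads in replicate 1. Against the floor they were 10.1-fold and 9.62-fold higher, with lower 95% counting limits of 7.53-fold and 7.16-fold. Gm45233 (0 and 65 reads), Podn (0 and 41) and Lncpint (0 and 37) were carried mostly by single-exon genomic models, and Pcdhga2 (0 and 21) by an incomplete model. The processed pseudogenes Gm8186, Gm6563 and Gm10774 completed the set and are uncertain.

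In all, 1813 of 8973 genes tested were called by Fisher's exact test, 792 higher in replicate 1 and 1021 in replicate 2, a share of 43.7% for replicate 1. With total scaling the calls were 1113 and 810, or 57.9%. In simulated libraries with the measured spread and no true difference the same test called 1689 of 8831 genes. That spread was measured between these same libraries, so the number does not separate replicate spread from a real difference. With edgeR's exact test and the common dispersion 11 genes passed, 1 higher in replicate 1 and 10 in replicate 2, and 476 had an unadjusted p under 0.05. The 11, chosen by that test after their values were seen where the rule did not name them, were Sln, Gm45233, A530058N18Rik, Gm10774, Gm6563, Rbp4, Podn, Gm8186, Lncpint, Gm28006 and Ddx6. Sln was the 1 among them with all its reads in an annotated, spliced protein coding model (log2 ratio -5.43). The edgeR test set 1 library against 1 and took its dispersion from these same libraries. It therefore does not separate replicate spread from a real difference either. With the length trend removed 867 genes were called, 601 of them also in the main set.

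Most reads belonged to annotated models. Known models held 69.9% of reads in replicate 1 and 69.6% in replicate 2, a mean of 69.8% ± 0.188 (SD, n = 2). In each class the 95% Wilson intervals of the libraries did not overlap. NNC models held 13.4 and 4.88% (9.15% ± 6.03), NIC models 4.81 and 3.05% (3.93% ± 1.25) and incomplete splice matches 8.35 and 11.9% (10.1% ± 2.48). Genomic models held 1.98 and 6.001%, antisense models 1.21 and 3.78% and intergenic models 0.348 and 0.813%. Known, NIC and NNC models together held 88.1% in replicate 1 and 77.6% in replicate 2. These shares are of all reads, with spike-ins and models of a single exon included. A single gene, Atp2a1, carried much of the NNC class, with 131695 and 33609 reads in 1 chain.

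**Figure D4:**
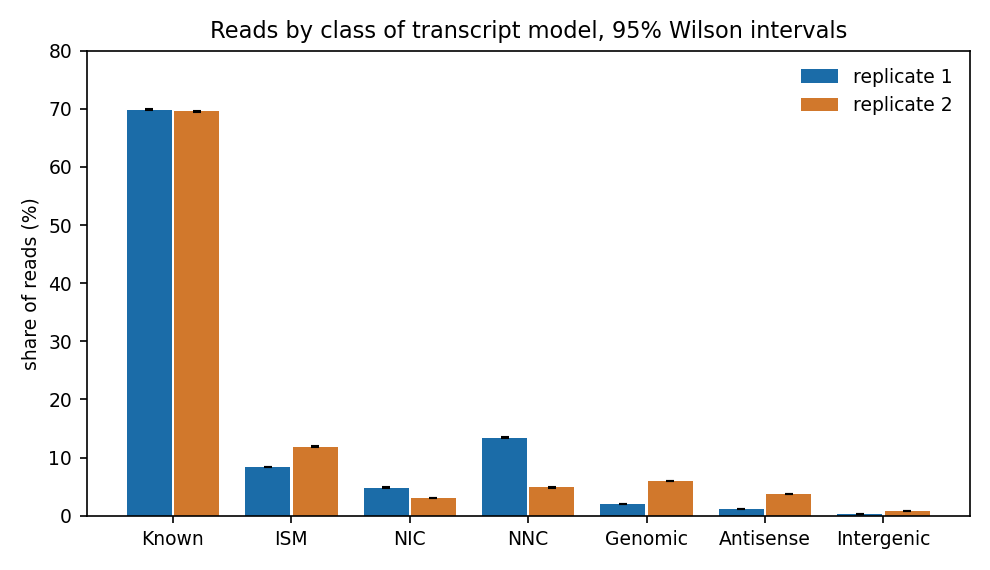
Percent of all reads in each class of transcript model in replicate 1 and replicate 2. Known models hold close to 70% in both, NNC models are larger in replicate 1 and incomplete, genomic, antisense and intergenic models are larger in replicate 2.

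Genes mostly used the same major splice chain in both libraries. Of 1455 genes with at least 50 full splice reads in each library, 1432 (98.4%, 95% Wilson interval 97.6 to 98.9%) had the same major chain, and this chain held a median of 94.5% of full splice reads in replicate 1 and 94.1% in replicate 2. The major chain was annotated in 1386 genes, NIC in 49 and NNC in 20. Pkm, which makes muscle or embryonic pyruvate kinase by a choice of exons, used Pkm-202 for 94.8% ± 0.00811 (SD, n = 2) and Pkm-201 for 2.00% ± 0.364. Myl1 used Myl1-202 for 62.5% ± 6.39 and Myl1-201 for 29.7% ± 7.05. Tpm1-205 held 98.7% ± 0.0232 of Tpm1, Tpm2-202 held 96.1% ± 0.646 of Tpm2, Des-201 held 99.3% ± 0.126 of Des and Acta1-201 held 98.8% ± 0.139 of Acta1. Ndrg2 was split between an NIC chain with 47.3% ± 0.628 and Ndrg2-201 with 45.1% ± 0.0115.

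Of the 70 genes of the isoform list 38 were deep enough, and 34 of these had the same major chain in both libraries. The major chain was annotated in 28 and unannotated in 10. Bin1, which shapes the T-tubule membrane, used an NNC chain for 54.5% ± 0.412 (SD, n = 2) and an NIC chain for 38.1% ± 1.92. Both held an exon of 45 bases outside the annotation (chromosome 18, 32423242 to 32423286), kept in 978 of 997 reads in replicate 1 and 547 of 561 in replicate 2, a mean of 97.8% ± 0.417. That exon was singled out after its values were seen. Neither of its ends is an annotated splice site, although the tables class the second chain as NIC. Fhl1 used Fhl1-204 for 63.4% in replicate 1 and 79.1% in replicate 2. The fast troponin T gene Tnnt3 spread over 186 chains, the largest with 19.6% ± 4.80. Its annotated exon of 14 bases was in 0 of 1086 spanning full splice reads in replicate 1 and 0 of 1167 in replicate 2. Loss of very short exons in alignment was not told apart from splicing there, so the chains of Tnnt3 are uncertain. Use differed in 10 of the 38 (permutation test, two-sided), among them Myl1 with an 11.04-point shift, Fhl1 with 19.1 points, Tnnt3 with 19.5 points and Trdn with 56.4 points, and in 12 adjusted over the list alone. The points sum the shares gained in replicate 2 over all chains of a gene, which also grow by sampling where chains are many and reads few. Trdn had 134 chains for 208 and 193 full splice reads, so the size of its shift is uncertain. The major chain of replicate 1 held 9.62% of Trdn there and 6.74% in replicate 2. For Myl1, Fhl1, Tnnt3 and Trdn the permutation p was 0.0001, the smallest that 10000 tables can give.

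Across all 1417 genes tested for chain use, 56 differed, 16 of them by at least 20 points. The largest shift, chosen by size after the values were seen, was in Srl, sarcalumenin, a calcium-binding protein of the sarcoplasmic reticulum lumen. Its usage differed by 72.6 points, and the major chain of replicate 1 held 67.7% there and 15.4% in replicate 2. Reads that skip exon 2 of Srl-201 numbered 2930 in replicate 1, above the 1852 full splice reads of Srl there. Many were thus in incomplete models, which chain use leaves out. In replicate 2 they were 884, against 1218 full splice reads. With incomplete models counted, inclusion of this exon was 30.2% in replicate 1 and 17.5% in replicate 2, so the size of the shift is uncertain. Transcript length differed between the libraries as described above, and whether chain use within a gene follows length was not tested. Counting incomplete matches as chains of their own gave 174 genes that differed.

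Exons of Bin1, Gnas, Mybpc1, Trdn and Nfix were among those held by a part of the reads in both libraries. Of 22939 internal exons in 3067 genes, 330 in 267 genes were included at 10 to 90% in both, and their inclusion differed by a median of 4.86 points. The limits apply to both libraries, which leaves out exons alternative in a single library, so this median is not a measure of how alike the libraries were. Of the 330, 285 were annotated and 190 lay wholly in coding sequence. Lengths were a multiple of 3 in 213 of them (64.5%) and in 7744 of the 19837 exons included at 99% or more (39.0%), which differed by Fisher's exact test over exons (two-sided, p = 2.7e-20). Exon 16 of Bin1-201, 72 coding bases on chromosome 18 from 32431671 to 32431742, was included at 59.2% ± 1.77 (SD, n = 2). Exon 3 of Gnas-201, 45 coding bases on chromosome 2 from 174336747 to 174336791, was at 84.1% ± 1.57, which separates the long and short forms of the stimulatory G protein. Exon 27 of Mybpc1-201, 59 coding bases on chromosome 10 from 88521277 to 88521335, was at 24.0% ± 1.34. Exon 20 of Trdn-201, 48 coding bases on chromosome 10 from 33343076 to 33343123, was at 84.0% ± 1.14, and exon 7 of Nfix-202, 123 coding bases on chromosome 8 from 84723728 to 84723850, at 36.9% ± 0.486. Ybx3, Slc16a3, Tecr, Mlf1, Smpx, Ywhae, Eif4g2, Tmed2, Ctbp1, Asph and Ndufs1 held further deeply covered alternative exons, from 13.1% ± 3.13 in Ndufs1 to 87.1% ± 1.301 in Mlf1.

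Inclusion differed between the libraries for 3 exons, for 5 without incomplete models and for 1 in known models alone. Exon 22 of Atp2a1-201, 42 bases of coding and untranslated sequence on chromosome 7 from 126446545 to 126446586, is the exon whose skipping gives the neonatal form of the calcium pump. It was included in 96.4% of 142473 reads in replicate 1 (95% Wilson interval 96.3 to 96.5%) and in 92.8% of 38777 in replicate 2 (92.5 to 93.0%), a mean of 94.6% ± 2.58 (SD, n = 2; Fisher's exact test, two-sided, adjusted p = 2.3e-185). Exon 2 of Srl-201, 1311 coding bases on chromosome 16 from 4496405 to 4497715, was included at 30.2% in replicate 1 and 17.5% in replicate 2 (adjusted p = 1.6e-13, Fisher's exact test). An exon of 1092 bases in Ndufv3, a subunit of respiratory complex I (chromosome 17, 31527310 to 31528401), was at 8.83 and 1.92% (adjusted p = 0.0012, Fisher's exact test). Inclusion of these long exons lengthens the transcript, and both were lower in replicate 2, which held shorter models. The Ndufv3 exon was named after its values were seen.

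**Figure D5:**
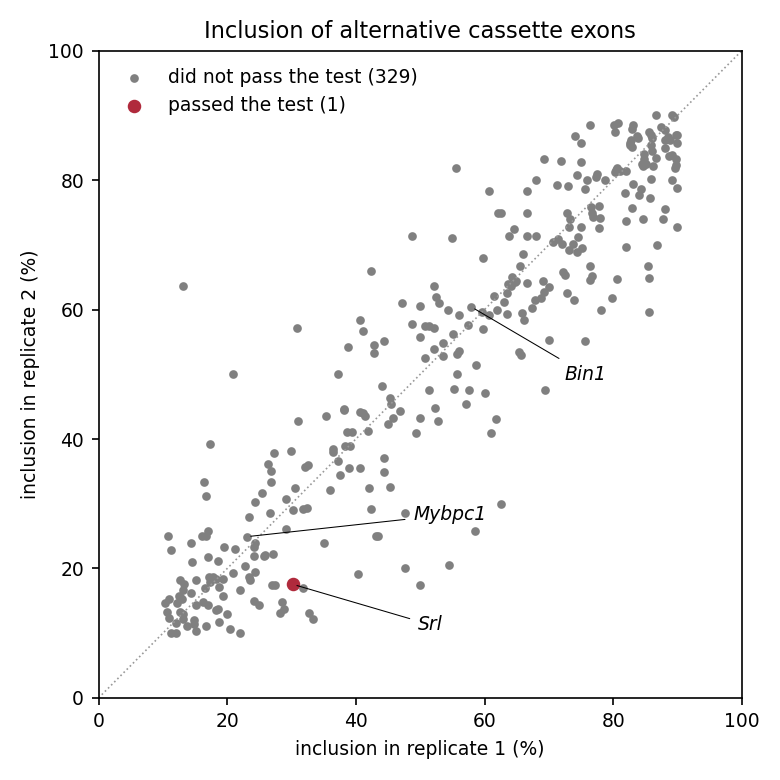
Inclusion of 330 alternative exons in percent of informative reads, replicate 1 (horizontal) against replicate 2 (vertical), with 1 point per exon and the exon of Srl that passed the test in red. Only exons within the limits in both libraries are shown, and their median difference was 4.86 points.

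Unannotated chains were mostly found again when they were deep. Of 6731 NIC and NNC chains with at least 2 reads in replicate 1, 57.6% (95% Wilson interval 56.4 to 58.8%) had a read in replicate 2. Of 4299 in replicate 2, 74.7% (73.4 to 76.0%) had a read in replicate 1, and the mean was 66.1% ± 12.1 (SD, n = 2). With at least 10 reads the mean was 96.6% ± 0.155. The chain with the most reads was an NNC chain of Atp2a1 with 22 exons, which held 94.6 and 90.7% of the gene's full splice reads and lacked the annotated exon of 18 bases on chromosome 7 from 126462500 to 126462517. An NIC chain of Aldoa held 10313 and 4571 reads, 71.6% ± 11.6 of its full splice reads, and an NNC chain of Myh4 held 10770 and 1189, 53.7% ± 3.00. The NIC chain of Tnni2, fast troponin I, held 92.9% ± 1.85. An annotated exon of 7 bases in Tnni2 was in 0 of 4262 spanning reads in replicate 1 and 0 of 2880 in replicate 2. The NIC chain of Oaz1, a gene whose protein is made by a ribosomal frameshift, held 96.7% ± 0.532. It differed from Oaz1-207 only in having no break where the annotation skips 1 base. A further chain of Atp2a1 and chains of Ndrg2, Acta1, Eno1 and Idh3b made up the other deepest ones. Of 27 annotated exons of at most 20 bases, 18 were in under 50% of the spanning reads. Chains that differ from the annotation at such an exon are therefore uncertain, among them those of Atp2a1 and Tnni2.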

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

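The length test over spike-ins, the test of RNA integrity as the whole cause and the test of the Pdk4 set against transcript length were chosen only after the results were seen. Signals in parts of the tables that enter no comparison, above what a count of 0 allows, brought the following values here. The antisense locus with the most reads, on chromosome 9 from 77654756 to 77660127 and opposite to Klhl31, had 1522 reads in replicate 1 and 6082 in replicate 2. The locus classed as intergenic with the most reads, on chromosome 11 from 20334834 to 20335012 where it overlaps the annotated Gm12033, had 1295 and 559. Reads antisense to spike-ins numbered 368 in replicate 1 and 226 in replicate 2.

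The log2 ratio of replicate 1 to replicate 2 rose with transcript length, and a bias in library making or sequencing and lower RNA integrity in replicate 2 were weighed. The ERCC spike-ins, which never were in the tissue, showed the same direction, with a Spearman's rho of 0.687 over 38 species (permutation p = 2e-05, two-sided), which is consistent with a bias of the libraries. Their slope was 0.896 per doubling of length (95% bootstrap interval 0.685 to 1.203), so tissue RNA integrity cannot be the whole cause. As a part of the cause it was not told apart, since the slope of tissue genes minus that of the spike-ins was -0.201 (-0.510 to 0.0243). No biological explanation was tested.

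The most read model of Atp2a1 was an unannotated chain without the annotated exon of 18 bases, and loss of very short exons in alignment and a splice form that differs between the animals were weighed. Among 27 annotated exons of at most 20 bases that all annotated transcripts across them hold, the median share of spanning reads with the exact exon was 0%, against 100% for exons over 100 bases. The set was split, since 18 were in under 50% of these reads and 9 in over 90%, among them the 18-base exons of Atp2a2 (95.6%) and Trdn (99.3%), so alignment loss by length alone stays open. The exact exon was in 0.000719 percentage points more of the spanning reads in replicate 1 than in replicate 2. With a share near 0 in both libraries this test decides nothing, and a form that differs between the animals cannot be told apart from loss in alignment.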

How the results depend on the processing

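The alternatives for transcript length, full splice models, spike-ins and Atp2a1 were chosen only after the data were seen. The Myh4 difference between the libraries turned its direction in full splice reads. The balance of genes higher in replicate 1 and in replicate 2, 792 and 1021, turned to 1113 and 810 with total scaling, 982 and 919 without genomic models, 861 and 718 in known models and 895 and 850 in full splice models. It moved the other way to 350 and 827 with at least 50 reads, and stood at 366 and 501 with the length trend removed. In full splice models, 5 genes were called in the other direction, Desi1, Esrra (log2 ratio -3.33 to 1.42), Gabarapl1, Tpr and Vps37b, chosen after their values were seen. Called the same here is a level within 1 SD of the libraries, a count within 1.5 times or an unchanged call. The SD of 2 libraries can be large, so levels called the same include the Schwann list at 694 CPM without genomic models against 1596, the mitochondrially encoded list at 666 to 2450.2 CPM and the NNC share at 4.88 to 13.4% in single libraries. Of the values that answer a comparison 41 stayed the same and 29 moved, and of those for single lists or genes 180 stayed, 28 moved, and 2 lost their call, in full splice models. A single library always lies within 1 SD of the mean of 2, so levels could not move when a replicate was left out. The percent of genes with an annotated major chain was called the same there without a limit. Leaving out replicate 1 and replicate 2 gave 43 and 42 of the values called the same, so part of this tally was fixed in advance. In known models alone the slow list held 4124 CPM against 6875, Myh1 33.4%, Myh7 11.96% and Myh3 0.284% of myosin reads, and without Atp2a1 the NNC share was 2.91%. The known share became 68.7% without spike-ins, 71.6% in genes with at least 10 reads in each library and 75.2% without Atp2a1. Genes detected were 12183 with a minimum of 1 read and 3891 with 20. The biological coefficient of variation was 0.389 with DESeq2 size factors, 0.387 with total scaling, 0.428 without a filter, 0.404 without genomic models, 0.412 in known models and 0.296 with the length trend removed. Genes that differ were 1177 with at least 50 reads, where fewer were tested, 11 in edgeR's exact test and 867 with the length trend removed. The Myh4 share was 49.0% in known models, which leave out its main chain, and 68.3% in full splice chains. Genes with different chain use were 35 in known models and 174 with incomplete matches as chains. The same major chain was used in 96.6% of genes at 20 reads, 99.4% in known models and 97.1% with incomplete matches. Alternative exons numbered 610 at 10 informative reads, 113 at 50, 121 in known models, 182 at 20 to 80% inclusion and 438 to 813 in a single library, where the inclusion limit and the read minimum both apply to that library alone and 23692 and 39419 exons are measured. Shared unannotated chains were 27.8% at 1 read, 91.1% at 5 and 96.6% at 10. Unless stated, the cause was not tested. No paired analysis was possible because there is 1 group.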

Other observations

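The test of the Pdk4 set against transcript length was chosen only after the result was seen, and the gene list used here was added then as well. Genes that respond to fasting and glucocorticoids in muscle were higher in replicate 1. The list of 30 genes, of which 3 are also in a list fixed before, held 0.153% ± 0.0785 of gene reads (SD, n = 2). Of 25 tested, 14 were higher in replicate 1 and 1 in replicate 2 by Fisher's exact test, and 16 and 1 adjusted over the list alone. With the length trend removed 11 and 1 passed, and Cebpb, Mt1 and Mt2 among the 11 had not been called before. The ubiquitin ligases of muscle wasting Trim63 (235 and 77 reads, log2 ratio 1.14) and Fbxo32 (49 and 9, 1.92), the glucocorticoid-induced Tsc22d3 (413 and 126, 1.25) and the lipid regulator Lpin1 (68 and 10, 2.25) were higher in replicate 1. The translation repressor Eif4ebp1 was higher in replicate 2 (113 and 212 reads, log2 ratio -1.36).

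Pdk4, Slc25a25, Arrdc2, Sgk1 and Cebpd, a set chosen after its values were seen, were higher in replicate 1, and transcript length and a fasting or glucocorticoid response were weighed. Their median log2 ratio after the length trend was 2.82 (smallest 2.00, largest 3.68), so length did not account for it. The median of the fasting and glucocorticoid list after the length trend was 1.16, at percentile 100 of random lists (central 95% from -0.26 to 0.34), which is consistent with such a response as a hypothesis. The list was added after these genes were seen, feeding and handling of the animals are not given in the sources used here, and a single library stands on each side.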
